A study of Mus musculus with 81 samples.

How the data were processed

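Microglia of adult male mice were sorted by flow cytometry, and polyadenylated RNA of pooled brains was sequenced as strand-specific libraries. The 81 libraries, in 28 groups of genotype, diet and gate, were taken as 5 experiments: WT and Trem2KO at baseline and 4 weeks of cuprizone (23 libraries), Cre and Mef2aKO at baseline and 5 weeks (29), Cre and Mef2aKO baseline gates (11), Cre and Egr2KO at baseline and 6 weeks (23), and Cre and Egr2KO whole populations at 5 weeks (4). The 3 Cre baseline libraries serve 3 of these experiments, so their comparisons share a control. Baseline cells were gated as CD44, CD45 and CD11b low per the labels.

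The 6 deposited tables used hold raw read counts per gene, with 25124 genes and 1 RefSeq transcript per gene; all values were whole numbers. Per the submitters' processing notes the tools were fastp 0.20.0, STAR 2.7.0f, HOMER 4.11 and DESeq2 with the mm10/GRCm38 genome, and the notes do not give each tool's role. Deposited TPM tables hold the same libraries and were not used here. Pairs of replicates differed by 1.565 to 16.132 times the chi-square of counting noise alone (median 4.429). Variation between libraries, rather than depth, set the precision of expressed genes.

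WT and Trem2KO cuprizone libraries are in different tables that share the WT baseline libraries. These tables keep different transcripts for 1560 genes. Genes were joined where the shared libraries held identical counts (24910 genes, of which 1346 list different transcripts), and the other 214 were left out of that experiment.

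Each experiment was fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM, 1 mean per group, quasi-likelihood F tests), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fits tested 12647, 13204, 12628, 13187 and 12387 genes with 16, 19, 7, 15 and 2 residual degrees of freedom. There were 30 comparisons, of which 3 were interactions. SEs come from the quasi-likelihood fit. Where a group had no read of a gene, its level and not its fold is given. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, correlation 0.01, lists of 3 or more measured genes, adjusted over the lists of a comparison), and again with an estimated correlation.

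The 26 lists were homeostatic microglia, disease-associated microglia, interferon response, MHC class II, MHC class I, cholesterol synthesis, cholesterol export and lipid storage, lysosome, inflammatory cytokines, immediate early genes, cell cycle, glycolysis, complement and Fc receptors, TREM2-DAP12 signaling, lineage transcription factors, Polycomb, and markers of oligodendrocytes, astrocytes, neurons, endothelium, T and NK cells, B cells, neutrophils, monocytes, border macrophages and dendritic cells. No gene is in more than 1 list. Of the border macrophage markers, 4 of 8 exceeded 5 CPM in Cre baseline cells. The comparisons, lists, the alternative settings other than those named as chosen later and the rule for named genes were chosen before the data were examined.

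Named genes were the sorting and target genes (Ly9, Itgax, Clec7a, Trem2, Mef2a, Egr2), and, among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, those with the largest fold changes (up to 8 per direction in 8 comparisons and 3 in the others, without predicted genes and small RNAs). Up to 4 members of each list past camera's test with the smallest adjusted p were added, and the text takes them from the top of each part, except 2 genes that are not reported here. Close paralogs, among them the Ifi200 family and class I H2 genes, can share reads, so their single levels are uncertain.

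Replicate numbers were checked for pairing by correlating residuals of same-numbered libraries. Only the 6-week CD229 step had every pair over 0.1 (0.17 to 0.29). A replicate block gave 2657 genes there, and a block nested in genotype and diet 3194, against 2269 without a block. A PE150 tag, whose meaning the labels do not state, is in 17 library titles: 2 of 3 libraries in each 6-week gate of both genotypes, both Egr2KO baseline libraries, and some Mef2aKO baseline gate libraries.

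Simulated counts had the groups and spread of 5 comparisons, with 100 genes at a 2-fold and 100 at a 4-fold change. The test recovered 77 to 84 and 93 to 97, with 6 to 14 false calls. Median folds were 1.97 to 2.01 and 3.95 to 4.02. Camera found a raised list in each and called 0 of 20 unchanged lists. This leaves lists of correlated genes unchecked.

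Alternatives were DESeq2's size factors (RLE) in edgeR, no filter, DESeq2 1.42.0, only the compared groups, replicate blocks, the PE150 tag as a covariate, and each library left out in turn. Others chosen after seeing the data were PE150 libraries only, libraries without PE150 only, each baseline control library in turn as the only control, and other joins of the 4-week tables. Positions of changed genes were tested in windows of 10 Mb holding at least 10 tested genes with Fisher's exact test, and correlations by 100000 permutations. Figures used matplotlib 3.10.9 in Python 3.11.15.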

Results

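Polyadenylated RNA was sequenced from microglia, the resident macrophages of the brain, sorted from adult male mice. The 81 libraries fell into 28 groups. Mice were fed a regular diet (baseline) or 0.2% cuprizone, a copper chelator that kills oligodendrocytes and strips myelin, for 4, 5 or 6 weeks. Cells were gated on the surface proteins CD229 (encoded by Ly9), CD11c (Itgax) and, at 5 weeks, Clec7a, a lectin receptor of activated microglia. Control mice were C57BL/6 (WT) or carried only the Cx3cr1 Cre driver (Cre). The other mice were Trem2KO, lacking a lipid-sensing receptor, or lacked a transcription factor in cells with that driver (Mef2aKO, Egr2KO). Groups held 3 libraries, except 4 in each Trem2KO cuprizone gate and 2 in Mef2aKO Clec7aneg, Mef2aKO baseline CD229pos, Egr2KO baseline and both whole-population groups. Total counts ran from 4387075 to 13972985 per library. Below, levels are group means in CPM ± SD, and log2 fold changes are given ± SE. Each gene list is given with its genes past the test over all genes and over the list alone, and with camera's adjusted p at a preset correlation between genes and, as "estimated", at the correlation estimated from the libraries.

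Trem2 (chromosome 17, 48346401 to 48352276, mm10) separated the Trem2KO libraries from the WT ones. Its level was 346.1 to 403.5 CPM in the 3 WT baseline libraries and 88.5 to 123 CPM in the 3 Trem2KO baseline libraries. In cuprizone it was 487 to 714 CPM over the 9 WT libraries and 120.0 to 166 CPM over the 8 Trem2KO libraries, so reads remained but no library overlapped. The Trem2 log2 fold change was -1.85 ± 0.09, adjusted p = 3.51e-13 at baseline, -2.06 ± 0.09 in CD229neg and -2.06 ± 0.09 in CD229pos cells.

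Mef2a (chromosome 7, 67231163 to 67372858) kept its reads in every Mef2aKO library. It stood at 861 ± 61.5 CPM in Mef2aKO and 972 ± 83.4 CPM in Cre baseline cells (-0.17 ± 0.08, adjusted p = 0.248), and its log2 fold change was 0.17, 0.05, 0.15 and -0.06 in the 4 gates at 5 weeks. Gene-level counts cannot show loss of a single exon, so Mef2a does not check those labels. Egr2 (chromosome 10, 67537869 to 67542188) was near 3.41 ± 1.09 CPM in Cre and 3.52 ± 1.15 CPM in Egr2KO baseline cells, so it was not lower there. After 6 weeks it was lower in Egr2KO by -0.88 ± 0.25 in CD229neg (adjusted p = 0.286), -0.62 ± 0.20 in CD229pos (adjusted p = 0.103) and -0.43 ± 0.18 in CD229pos CD11cpos cells (adjusted p = 0.487), and no gate passed the test, while all 3 passed without a filter (adjusted p = 6.25e-06, 5.45e-05 and 0.0119). Within the libraries tagged PE150 in their titles (n = 2 each) it was -0.99 (adjusted p = 0.0347), -0.67 (adjusted p = 0.024) and -0.36 (adjusted p = 0.321), and in CD229pos cells it also passed without Cre replicate 1 (adjusted p = 0.0246). Individual Egr2KO libraries lay at 9.88 to 11.6, 22.4 to 42.1 and 77.2 to 87.5 CPM, against 14.2 to 26.1, 32.3 to 60.4 and 97.5 to 119 CPM in Cre. In the whole population at 5 weeks Egr2 fell from 68.2 ± 1.09 to 22.1 ± 5.44 CPM (-1.61 ± 0.14, adjusted p = 3.94e-05, n = 2 each).

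**Figure D1:**
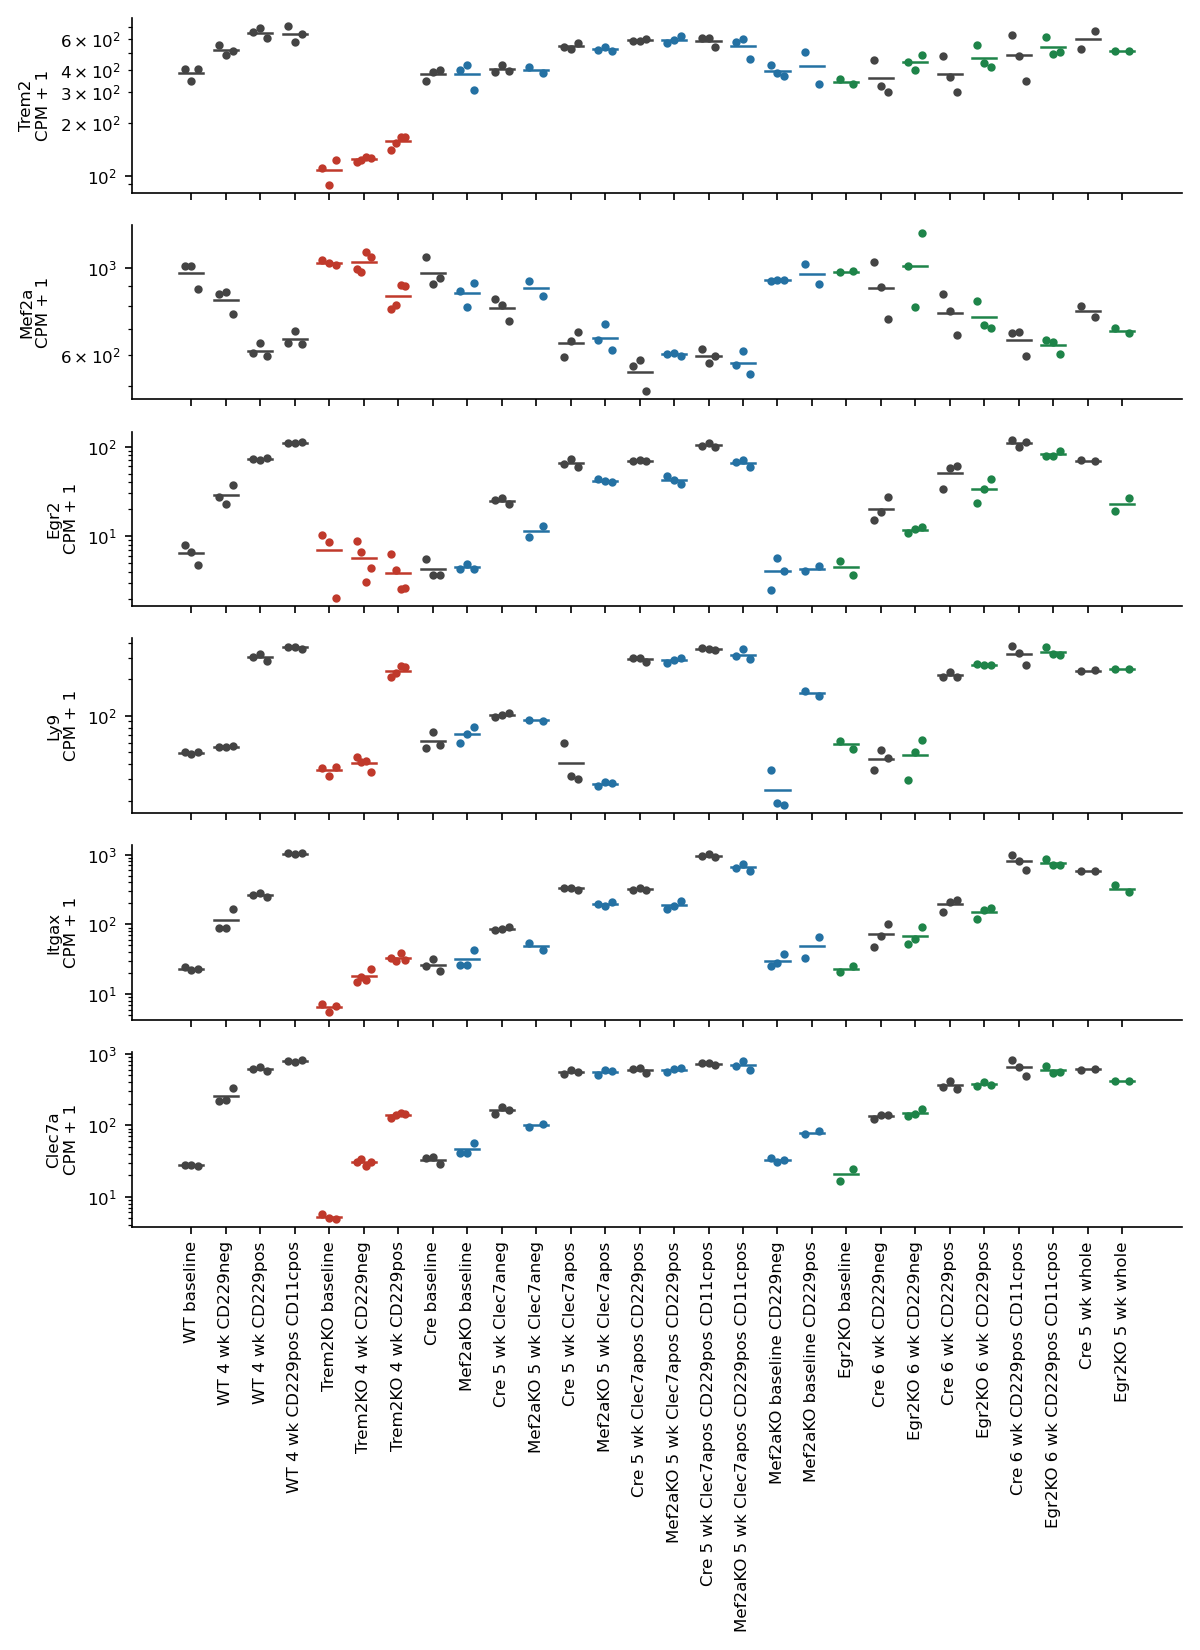
Levels of Trem2, Mef2a, Egr2, Ly9, Itgax and Clec7a in every library on a log axis (CPM + 1), by group. Points are libraries and bars are group means. The Trem2KO libraries lie below every other library for Trem2, and Mef2aKO libraries overlap the controls for Mef2a.

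WT CD229neg cells after 4 weeks of cuprizone were set against WT baseline cells (n = 3 each). Baseline was not gated on CD229 or CD11c, so all diet steps mix diet and gate. Fn1, which encodes fibronectin, rose from 1.2 ± 1.41 to 834 ± 209.5 CPM (9.37 ± 0.32, adjusted p = 4.52e-18). Lgi2, a secreted leucine-rich repeat protein, rose by 9.22 ± 0.60, and Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, by 8.35 ± 0.36, adjusted p = 5.97e-16. Adamtsl2, a matrix protein, and Gpr165, an orphan receptor, fell by -1.31 ± 0.19 and -1.27 ± 0.14. Clec7a rose by 3.29 ± 0.12 and Itgax by 2.38 ± 0.17, while Ly9 did not pass (0.17 ± 0.09, adjusted p = 0.145). Disease-associated microglia genes, led by Lpl (4.01 ± 0.12) and Cst7 (4.96 ± 0.17), rose (24 of 24 rose, 24 adjusted over the list alone, camera adjusted p = 8.22e-24, estimated 0.0212). The interferon list rose (25 of 25 rose, 25 adjusted over the list alone, camera adjusted p = 2.24e-29, estimated 0.0254), with the sensor Oasl2 at 3.52 ± 0.18. So did the cell cycle list (25 of 25 rose, 25 adjusted over the list alone, camera adjusted p = 3.77e-21, estimated 0.0659), with the kinase Cdk1 at 2.69 ± 0.24. edgeR called 3850 genes, 2374 higher and 1476 lower, of which 672 and 95 moved at least 2-fold.

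The CD229 step at 4 weeks, WT CD229pos against WT CD229neg cells (n = 3 each), changed the most genes of the WT steps, 3112 higher and 3056 lower. Ly9 rose from 55 ± 0.703 to 305 ± 20.7 CPM (2.47 ± 0.08, adjusted p = 1.06e-17), as gated. Ace, the angiotensin-converting enzyme, rose by 2.53 ± 0.59, Mamdc2, a secreted proteoglycan, by 2.44 ± 0.23, and the lipoprotein gene Apoc4 by 2.31 ± 0.29. Setbp1, a chromatin-linked protein, fell from 10.4 ± 1.04 to 0.444 ± 0.32 CPM (-4.55 ± 0.29, adjusted p = 1.27e-12), Gpr165 fell by -4.34 ± 0.22, and the endothelial-type adhesion regulator Tmem204 fell by -3.78 ± 0.20. Homeostatic microglia genes fell (2 rose and 14 fell of 20, 2 and 15 adjusted over the list alone, camera adjusted p = 2.63e-05, estimated 0.423), led by Upk1b, a tetraspanin, at -2.88 ± 0.14. Glycolysis genes rose (14 rose and 1 fell of 15, 14 and 1 adjusted over the list alone, camera adjusted p = 1.55e-07, estimated 0.26), with Gpi1, an early enzyme of the pathway, at 0.84 ± 0.06. Cell cycle genes rose as well (25 of 25 rose, 25 adjusted over the list alone, camera adjusted p = 5.34e-06, estimated 0.423). So did disease-associated (23 of 24 rose, 23 adjusted over the list alone, camera adjusted p = 6.48e-10, estimated 0.244) and interferon genes (22 of 25 rose, 22 adjusted over the list alone beside 1 lower, camera adjusted p = 5.34e-06, estimated 0.423). Endothelial markers split (2 rose and 2 fell of 4, sum 118 ± 16.7 to 311 ± 12.1 CPM), as did astrocyte markers (1 and 1 of 7, sum 145 ± 4.43 to 94.7 ± 7.04 CPM), with camera adjusted p = 0.901 each. In the DESeq2 fit Ace no longer passed (adjusted p = 0.13).

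Among CD229pos cells, those that also carried CD11c were compared with those that did not (n = 3 each). Postn, periostin, rose from 7.02 ± 0.78 to 158 ± 12 CPM (4.47 ± 0.15, adjusted p = 4.74e-18). Stra6l, a retinol transporter, rose by 3.69 ± 0.23 and the macrophage elastase gene Mmp12 by 3.28 ± 0.26. Apob, an apolipoprotein, fell by -3.29 ± 0.44, and Epha2, an ephrin receptor, by -2.17 ± 0.17, adjusted p = 6.77e-10. Itgax rose by 1.97 ± 0.14, Trem2 did not change past the test (-0.02 ± 0.09, adjusted p = 0.898), and Ly9 rose by 0.26 ± 0.07, adjusted p = 0.0109. The Ly9 call ended without 1 library (adjusted p = 0.101 without CD229pos replicate 3). The sugar transporter Slc2a5 led a fall of the homeostatic list (-1.25 ± 0.07, 2 rose and 11 fell of 20, 2 and 12 adjusted over the list alone, camera adjusted p = 4e-06, estimated 0.712). Unlike the CD229 step, this step lowered the cell cycle list (24 of 25 fell, 24 adjusted over the list alone, camera adjusted p = 3.41e-10, estimated 0.712), with the replication factor Mcm3 at -0.49 ± 0.08. It also lowered the glycolysis list (10 of 15 fell, 11 adjusted over the list alone, camera adjusted p = 0.000862, estimated 0.712), with Ldha at -0.50 ± 0.08. Counts were 1496 higher and 1455 lower genes.

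At baseline, Trem2KO microglia differed from WT (n = 3 each) in few genes, 5 higher and 68 lower. Clec7a fell from 26.4 ± 0.306 to 4.19 ± 0.412 CPM (-2.65 ± 0.18, adjusted p = 1.28e-10), Itgax by -2.02 ± 0.25 and Ly9 by -0.49 ± 0.09, adjusted p = 0.00514. The lipase gene Lpl (-1.26 ± 0.15) and the receptor kinase Axl (-1.77 ± 0.23) led the disease-associated list (6 of 24 fell, 9 adjusted over the list alone, camera adjusted p = 7.78e-11, estimated 0.168). The astrocyte list moved down (2 of 7 fell, 3 adjusted over the list alone, camera adjusted p = 0.000636, estimated 0.145), led by Clu (-7.68 ± 1.22). Ccdc162 was the highest of the genes that rose (0.80 ± 0.16, adjusted p = 0.00896), a call that ended in 3 fits (adjusted p = 0.0987 without WT replicate 2, 0.0668 without WT replicate 3 or 0.0528 without Trem2KO replicate 1). The count of calls was 206 without WT replicate 1, 34 without WT replicate 2, 43 without WT replicate 3 or 44 without Trem2KO replicate 1. With WT baseline replicate 1, 2 or 3 as the only control, fits chosen after seeing the data, 12, 382 and 113 genes passed. Clec7a (-2.66, -2.65 and -2.63) and Lpl (-1.40, -1.37 and -0.94) passed each time. With replicate 1 Axl, Clu and Ccdc162 did not (adjusted p = 0.233, 1 and 1), and Ly9 passed with none (0.0502 to 0.242).

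In CD229neg cells at 4 weeks, Trem2KO (n = 4) against WT (n = 3) lowered genes raised in the WT diet step, Fn1 and Clec7a among them. Cspg4, a chondroitin sulfate proteoglycan, was at 0.321 ± 0.242 CPM in Trem2KO and 161 ± 49.7 CPM in WT (-8.96 ± 0.30, adjusted p = 2.58e-18). No read of Ass1, which makes argininosuccinate, was counted in any Trem2KO library, against 4.03 ± 1.6 CPM in WT (adjusted p = 7.78e-07), and Fn1 fell by -8.19 ± 0.26. Ccdc162, of unknown function, rose by 1.22 ± 0.17, adjusted p = 4.86e-06, and the sugar transporter Slc5a10 by 1.13 ± 0.24. Clec7a fell by -3.14 ± 0.10, Itgax by -2.77 ± 0.16 and Egr2 by -2.53 ± 0.33, adjusted p = 2.42e-06. The disease-associated list fell (23 of 24 fell, 23 adjusted over the list alone, camera adjusted p = 9.01e-23, estimated 0.0243), led by Lpl (-4.00 ± 0.11). Interferon (23 of 25 fell, 23 adjusted over the list alone, camera adjusted p = 1.57e-12, estimated 0.18) and cell cycle genes (22 of 25 fell, 25 adjusted over the list alone, camera adjusted p = 7.81e-08, estimated 0.29) fell too. MHC class II genes fell (6 of 8 fell, 6 adjusted over the list alone, camera adjusted p = 0.000399, estimated 0.18), with Cd74, the class II chaperone, at -2.40 ± 0.35. Border macrophage markers fell beside the class II genes (7 of 8 fell, 7 adjusted over the list alone, camera adjusted p = 0.0111, estimated 0.412), led by the platelet factor gene Pf4 (-4.10 ± 0.82). The 2568 calls (914 higher, 1654 lower) became 1362 without WT replicate 3.

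CD229pos cells showed the largest count of the Trem2KO comparisons (n = 4 against 3), 3282 genes higher and 3356 lower. Cspg4 was 0.675 ± 0.206 CPM in Trem2KO and 642 ± 26.1 CPM in WT (-9.83 ± 0.25, adjusted p = 4.89e-21), Fn1 fell by -7.97 ± 0.22 and the chemokine gene Cxcl14 by -6.93 ± 0.32. Adcy8, an adenylate cyclase, rose from 1.11 ± 0.156 to 12.9 ± 3.57 CPM (3.53 ± 0.31, adjusted p = 2.54e-10), Setbp1 by 3.44 ± 0.32, and the zinc transporter Slc39a12 by 3.35 ± 0.28. WT and Trem2KO counts use different transcripts for Fn1 and others, so its fall in both gates may reflect this. Ly9 differed little between the genotypes (-0.38 ± 0.07, adjusted p = 6.08e-05), while Itgax fell by -3.04 ± 0.15 and Egr2 from 71.5 ± 1.27 to 2.92 ± 1.73 CPM (-4.49 ± 0.33, adjusted p = 9.71e-12). Lpl (-4.09 ± 0.11) led the fall of the disease-associated list (23 of 24 fell, 23 adjusted over the list alone, camera adjusted p = 1.94e-11, estimated 0.287), and the glucose transporter Slc2a1 (-1.58 ± 0.08) that of glycolysis (1 rose and 13 fell of 15, 1 and 13 adjusted over the list alone, camera adjusted p = 2.83e-07, estimated 0.354). The lens crystallin gene Crybb1, a microglial maturity marker, rose by 1.88 ± 0.12 within the homeostatic list (10 rose and 3 fell of 20, 10 and 3 adjusted over the list alone, camera adjusted p = 0.0132, estimated 0.781), whose camera call ended without 1 library (WT replicate 3, adjusted p = 0.0675). Of 4 endothelial markers 2 rose and 1 fell (sum 66.6 ± 3.52 CPM in Trem2KO, 311 ± 12.1 in WT, camera adjusted p = 0.775), and of 7 astrocyte markers 1 rose (202 ± 9.28 and 94.7 ± 7.04 CPM, camera adjusted p = 0.751). Interferon genes did not move as a list (2 rose and 10 fell of 25, 2 and 10 adjusted over the list alone, camera adjusted p = 0.543).

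Inside the Trem2KO mice, CD229pos cells were compared with CD229neg cells (n = 4 each). Ly9 rose by 2.55 ± 0.07, adjusted p = 2.34e-19, Clec7a from 29.3 ± 2.86 to 138 ± 8.46 CPM (2.24 ± 0.10), and Egr2 did not pass (-0.61 ± 0.44, adjusted p = 0.332). Fabp5, a fatty acid carrier, rose by 3.67 ± 0.32, Mamdc2 by 3.59 ± 0.73 and the apolipoprotein gene Apoc1 by 3.42 ± 0.26. Ctnnd2, a catenin, fell by -2.45 ± 0.20 and Gpr165 by -1.89 ± 0.13. The interferon list rose (25 of 25 rose, 25 adjusted over the list alone, camera adjusted p = 1.68e-24, estimated 0.0618), led by Rsad2 (1.94 ± 0.14). The growth factor gene Igf1 (3.32 ± 0.21) led a rise of disease-associated genes (21 of 24 rose, 21 adjusted over the list alone, camera adjusted p = 3.26e-15, estimated 0.0618). The cell cycle list rose too (23 of 25 rose, 23 adjusted over the list alone, camera adjusted p = 2.04e-13, estimated 0.203). Border macrophage markers rose (6 of 8 rose, 7 adjusted over the list alone, camera adjusted p = 0.00205, estimated 0.403), led by the folate receptor gene Folr2 (2.17 ± 0.24). edgeR called 1875 genes higher and 1603 lower.

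Whether the CD229 step differed between Trem2KO and WT was tested as an interaction, Trem2KO minus WT, over 14 libraries. It differed past the test for 1871 genes (1141 positive, 730 negative). The largest positive differences were the class II gene H2-Aa (2.85 ± 0.76, adjusted p = 0.0107), Setbp1 (2.69 ± 0.37) and Adcy8 (2.68 ± 0.38), and the largest negative ones Pacsin1, a membrane-bending protein (-2.62 ± 0.27, adjusted p = 1.51e-07), the receptor gene Notch4 (-2.57 ± 0.21) and Kbtbd11 (-2.42 ± 0.43). The rise of Clec7a was larger in Trem2KO (0.97 ± 0.14, adjusted p = 1.77e-05), that of Ly9 did not differ past the test (0.08 ± 0.11, adjusted p = 0.702), and the difference for Egr2 (-1.96 ± 0.52, adjusted p = 0.00982) ended as a call in 1 fit (adjusted p = 0.0565 without Trem2KO CD229neg replicate 1). The interferon list had a larger step in Trem2KO (17 of 25 rose, 20 adjusted over the list alone, camera adjusted p = 8.04e-06, estimated 0.796), led by Oas2 (1.52 ± 0.29), and glycolysis a smaller one (7 of 15 fell, 9 adjusted over the list alone, camera adjusted p = 0.000531, estimated 0.796), led by Slc2a1 (-0.56 ± 0.11). The 8 border macrophage markers had a median difference of 2.29 beside that of H2-Aa, with none past the test (camera adjusted p = 0.119).

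At 5 weeks, Cre Clec7aneg cells, also without CD229 and CD11c, were compared with Cre baseline cells not gated on these proteins (n = 3 each). Fn1 rose from 1.08 ± 0.564 to 711 ± 139 CPM (9.34 ± 0.29, adjusted p = 5.82e-22), Gpnmb by 7.60 ± 0.37 and Lgi2 by 7.45 ± 0.53. Clec7a RNA rose by 2.32 ± 0.12 in these cells, Ly9 by 0.73 ± 0.14 and Egr2 by 2.83 ± 0.15. F13a1, a coagulation factor gene of monocytes and border macrophages, fell by -3.33 ± 0.50, adjusted p = 3.86e-06. Border macrophage markers fell with it (1 rose and 6 fell of 8, 1 and 6 adjusted over the list alone, camera adjusted p = 0.0181, estimated 0.479), led by Mrc1 (-2.04 ± 0.33), and that list's call ended without Cre baseline replicate 1 or 2 (highest adjusted p = 0.0777). With Cre baseline replicate 1, 2 or 3 as the only control, fits chosen after seeing the data, F13a1 and Mrc1 did not pass with replicate 3 (adjusted p = 0.368 and 0.863), nor Ly9 with replicate 2 (adjusted p = 0.0527). Interferon genes rose (25 of 25 rose, 25 adjusted over the list alone, camera adjusted p = 5.39e-31, estimated 0.00241), led by Oasl2 (2.67 ± 0.15). Cell cycle genes rose (26 of 26 rose, 26 adjusted over the list alone, camera adjusted p = 1.63e-29, estimated 0.0114), led by the proliferation antigen gene Mki67 (3.72 ± 0.21). Osteopontin (Spp1, 5.56 ± 0.21) led the disease-associated genes, which rose (20 of 25 rose, 21 adjusted over the list alone, camera adjusted p = 5.14e-23, estimated 0.0114). The chemokine gene Ccl12 (1.55 ± 0.13) led inflammatory genes (14 of 20 rose, 15 adjusted over the list alone beside 1 lower, camera adjusted p = 3.28e-09, estimated 0.00241). Atf3 (2.55 ± 0.15) led immediate early genes (20 of 20 rose, 20 adjusted over the list alone, camera adjusted p = 1.24e-14, estimated 0.0402). Calls numbered 2052 higher and 1756 lower.

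Clec7apos cells against Clec7aneg cells, both without CD229 and CD11c at the surface (n = 3 each), gave 2754 genes higher and 2245 lower. Clec7a rose from 160.1 ± 16.6 to 558 ± 30.7 CPM (1.80 ± 0.10, adjusted p = 1.91e-15), Itgax rose by 1.93 ± 0.12, and Ly9 fell by -1.30 ± 0.14, adjusted p = 7.85e-09. Dkk2, a Wnt inhibitor, rose by 4.27 ± 0.38, Mamdc2 by 3.78 ± 0.25 and the scavenger receptor gene Cd163 by 3.21 ± 0.63, adjusted p = 0.000119. Gpr165 fell by -2.42 ± 0.18 and Sec16b, an export-site protein, by -2.36 ± 0.24. Csf1, the colony-stimulating factor, rose by 1.70 ± 0.08 and led the disease-associated list (25 of 25 rose, 25 adjusted over the list alone, camera adjusted p = 1.71e-20, estimated 0.0335). The lipid genes of cholesterol export rose (13 of 18 rose, 13 adjusted over the list alone beside 1 lower, camera adjusted p = 1.3e-09, estimated 0.0335), led by the esterase gene Nceh1 (1.68 ± 0.09). The lysosome list rose (20 rose and 1 fell of 23, 20 and 2 adjusted over the list alone, camera adjusted p = 2.96e-08, estimated 0.197), led by Glb1 (0.89 ± 0.07). Border macrophage markers rose beside them (7 of 8 rose, 7 adjusted over the list alone, camera adjusted p = 0.000405, estimated 0.197), led by Folr2 (2.22 ± 0.14).

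The CD229 step within Clec7apos cells (n = 3 each) was smaller, with 277 genes higher and 453 lower, or 343 without Clec7apos replicate 3 or 385 without Clec7apos CD229pos replicate 1. Ly9 rose from 39.6 ± 16.5 to 291 ± 14.2 CPM (2.83 ± 0.14, adjusted p = 1.75e-15), while Clec7a (0.08 ± 0.10, adjusted p = 0.685) and Itgax (-0.04 ± 0.12, adjusted p = 0.887) did not pass. Hlf, a circadian transcription factor, fell by -2.43 ± 0.36, adjusted p = 4.16e-05, the zinc transporter Slc39a12 by -2.15 ± 0.36 and the semaphorin gene Sema4b by -1.84 ± 0.20. Upk1b (-1.07 ± 0.13) led the fall of homeostatic genes (9 of 20 fell, 12 adjusted over the list alone, camera adjusted p = 1.29e-06, estimated 0.727). Both here and in the 4-week WT CD229 step, 260 genes rose (67.9 for independent lists), 428 fell (108), and 1 moved the opposite way.

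The CD11c step at 5 weeks compared the triple-positive gate (Clec7apos CD229pos CD11cpos) with Clec7apos CD229pos cells (n = 3 each). Postn rose from 9.67 ± 1.28 to 180.5 ± 6.35 CPM (4.22 ± 0.13, adjusted p = 3.29e-22) and Myof, a membrane-repair protein, by 3.10 ± 0.15. Syt6, a synaptotagmin, fell by -2.54 ± 0.39 and the purine receptor gene P2rx1 by -2.21 ± 0.36. Itgax rose by 1.60 ± 0.12, Egr2 rose by 0.57 ± 0.10, adjusted p = 5.39e-05, and Ly9 did not pass (0.28 ± 0.12, adjusted p = 0.136). MHC class II genes rose (5 rose and 1 fell of 8, 5 and 1 adjusted over the list alone, camera adjusted p = 0.00883, estimated 0.156), led by Cd74 (1.87 ± 0.18) and H2-Aa (2.25 ± 0.28). The cell cycle list fell (25 of 26 fell, 25 adjusted over the list alone, camera adjusted p = 7.5e-15, estimated 0.156), led by Cenpf (-0.92 ± 0.13). Slc2a5 (-0.93 ± 0.07) led the fall of homeostatic genes (1 rose and 10 fell of 20, 1 and 12 adjusted over the list alone, camera adjusted p = 7.56e-07, estimated 0.655). There were 904 genes higher and 957 lower, or 1169 without Clec7apos CD229pos CD11cpos replicate 1.

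Mef2aKO baseline cells were compared with Cre baseline cells (n = 3 each), with 233 genes higher and 274 lower. Ifi202b, an interferon-inducible DNA-binding gene, was 3.18 ± 1.94 CPM in Mef2aKO and 0.0945 ± 0.0948 CPM in Cre (4.92 ± 0.61, adjusted p = 3.03e-06). Close copies of it can share reads, so its level is uncertain. Lgi2 rose by 4.51 ± 0.90, adjusted p = 0.00166 and the aspartic protease gene Ctse by 2.95 ± 0.41, adjusted p = 1.15e-05. Myof fell by -3.03 ± 0.55, adjusted p = 0.000575, H2-Aa fell from 46.9 ± 28.7 to 6.06 ± 3.4 CPM (-2.93 ± 0.36, adjusted p = 1.73e-06), and the border macrophage gene Ms4a7 fell by -2.86 ± 0.39. Class II genes fell as a list (5 of 8 fell, 5 adjusted over the list alone beside 1 higher, camera adjusted p = 1.63e-07, estimated 0.00647), beside border macrophage markers (7 of 8 fell, 7 adjusted over the list alone, camera adjusted p = 3.71e-07, estimated 0.0911). The cell cycle list rose (12 of 26 rose, 20 adjusted over the list alone, camera adjusted p = 3.61e-21, estimated 0.0685), led by Mki67 (1.79 ± 0.23, adjusted p = 3.03e-06). The count became 301 without Cre replicate 1, 282 without Cre replicate 2 or 815 without Cre replicate 3. With Cre baseline replicate 1, 2 or 3 as the only control, chosen after seeing the data, 465, 320 and 137 genes passed. Ifi202b, Ctse, H2-Ab1 (-2.83, -2.81 and -1.39), Cd74 (-2.42, -2.22 and -0.98) and Mki67 (2.17, 2.41 and 1.13) passed each time. H2-Aa, Myof and Ms4a7 did not pass with replicate 3 (adjusted p = 0.142, 0.361 and 0.273), nor Lgi2 with replicates 2 and 3 (adjusted p = 0.111 and 0.191).

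In Clec7aneg cells at 5 weeks (Mef2aKO n = 2, Cre n = 3), Mef2aKO gave 214 genes higher and 516 lower, or 299 without Mef2aKO replicate 1. Ifi202b had no read in any Cre library and 7.06 ± 1.47 CPM in Mef2aKO (adjusted p = 1.03e-09). Mamdc2 had no read in Mef2aKO and 1.29 ± 0.271 CPM in Cre (adjusted p = 0.00132), and the plexin gene Plxna2 fell by -4.08 ± 0.51. Clec7a fell by -0.70 ± 0.12, Itgax by -0.85 ± 0.15 and Egr2 by -1.20 ± 0.15, adjusted p = 7.2e-07. Interferon genes fell (21 of 25 fell, 24 adjusted over the list alone, camera adjusted p = 2.32e-27, estimated 0.00857), led by Ifi204 (-2.53 ± 0.22). So did disease-associated genes (12 of 25 fell, 12 adjusted over the list alone, camera adjusted p = 6.35e-12, estimated 0.11), led by Gpnmb (-3.21 ± 0.26). Class II genes also fell (4 of 8 fell, 5 adjusted over the list alone beside 1 higher, camera adjusted p = 2.05e-05, estimated 0.0254), led by Cd74 (-2.08 ± 0.26), as did glycolysis genes (9 of 16 fell, 10 adjusted over the list alone, camera adjusted p = 1.77e-09, estimated 0.182), led by the lactate transporter Slc16a3 (-0.56 ± 0.08). Border macrophage markers moved down too (1 rose and 1 fell of 8, 1 and 4 adjusted over the list alone, camera adjusted p = 0.0049, estimated 0.281).

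Mef2aKO Clec7apos cells against Cre Clec7apos cells (n = 3 each) gave 194 genes higher and 294 lower, or 315 without Cre replicate 1. Ifi202b was 49.2 ± 2.96 against 0.121 ± 0.105 CPM (8.54 ± 0.39, adjusted p = 5.66e-16), Ctse rose by 2.44 ± 0.18 and Lgi2 by 1.92 ± 0.13. F13a1 fell by -3.77 ± 0.59, Cd163 by -3.26 ± 0.66, adjusted p = 0.00203, and Ifi213, a relative of Ifi202b with the same doubt over shared reads, by -2.84 ± 0.37. Clec7a did not pass (0.01 ± 0.10, adjusted p = 0.984), while Itgax (-0.75 ± 0.12) and Egr2 (-0.67 ± 0.10) fell. The disease-associated list moved down (6 of 25 fell, 7 adjusted over the list alone, camera adjusted p = 0.000616, estimated 0.483), led by galectin Lgals3 (-0.90 ± 0.10). Cholesterol synthesis rose as a list (2 of 20 rose, 7 adjusted over the list alone, camera adjusted p = 0.000629, estimated 0.0323). Border macrophage markers fell (4 of 8 fell, 4 adjusted over the list alone beside 1 higher, camera adjusted p = 0.00928, estimated 0.452), a call that ended without Cre Clec7apos replicate 1 (adjusted p = 0.0672).

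Clec7apos CD229pos cells (n = 3 each) had 276 genes higher and 371 lower in Mef2aKO, or 425 without Mef2aKO replicate 1 or 430 without Mef2aKO replicate 2. Ifi202b rose by 8.57 ± 0.36, Ctse by 2.12 ± 0.17 and the calmodulin-binding gene Pcp4 by 1.71 ± 0.25. Ifi213 fell by -2.62 ± 0.35, Mamdc2 from 26.4 ± 5.26 to 4.71 ± 1.44 CPM (-2.49 ± 0.20, adjusted p = 4.84e-10) and Ace by -2.11 ± 0.27. Itgax fell by -0.76 ± 0.12 and Egr2 by -0.71 ± 0.10, and Ly9 did not pass (-0.03 ± 0.12, adjusted p = 0.935). H2-Eb1 (-1.65 ± 0.30, adjusted p = 0.000419) led class II genes (5 of 8 fell, 5 adjusted over the list alone beside 2 higher, camera adjusted p = 0.0305, estimated 0.615), whose call ended without Cre replicate 1 or either of Mef2aKO replicates 1 and 2 (highest adjusted p = 0.0846). Border macrophage markers fell beside them (4 of 8 fell, 6 adjusted over the list alone beside 1 higher, camera adjusted p = 0.0178, estimated 0.615), a call that also ended without Cre replicate 1 (adjusted p = 0.0846). Cholesterol synthesis moved up (4 of 20 rose, 5 over the list alone, camera adjusted p = 0.00223, estimated 0.051).

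In the triple-positive gate (n = 3 each), Mef2aKO gave 309 genes higher and 310 lower, or 380 without Cre replicate 1. Ifi202b rose by 8.68 ± 0.36, Lgi2 from 32.2 ± 2.71 to 166 ± 16.7 CPM (2.36 ± 0.14, adjusted p = 1.49e-13) and Pcp4 by 2.07 ± 0.30. Ifi213 fell by -2.46 ± 0.31, adjusted p = 2.28e-06, Mamdc2 by -2.31 ± 0.16, Ace by -1.74 ± 0.23, the receptor gene Slamf7 by -1.72 ± 0.23, the oxidase subunit Cybb by -1.65 ± 0.18 and Postn from 180.5 ± 6.35 to 57.5 ± 3.55 CPM (-1.65 ± 0.11, adjusted p = 6.39e-13). Itgax (-0.55 ± 0.11) and Egr2 (-0.67 ± 0.10) fell and Clec7a did not pass (-0.09 ± 0.10, adjusted p = 0.806). Class II genes fell (1 rose and 5 fell of 8, 2 and 5 adjusted over the list alone, camera adjusted p = 0.00889, estimated 0.213), led by H2-Ab1 (-1.13 ± 0.18), and cell cycle genes rose (9 of 26 rose, 23 adjusted over the list alone, camera adjusted p = 2.05e-10, estimated 0.251), led by Cenpf (0.62 ± 0.13). The disease-associated list moved down (5 of 25 fell, 7 adjusted over the list alone, camera adjusted p = 0.000349, estimated 0.455), led by chemokine Ccl6 (-0.57 ± 0.09), a call lost without Mef2aKO replicate 3 (adjusted p = 0.215).

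In all 5 Mef2aKO gates 76 genes changed with 1 sign. Of these, 13 lay between 170 and 180 Mb of chromosome 1, Ifi202b and Ifi213 among them, a set chosen after seeing the values. Ly9 (CD229) lies there too, with effects on its gate untested. In that window 29 of 98 tested genes changed in the triple-positive gate (one-sided Fisher's exact test, adjusted p = 1.13e-13 over 252 windows), and 26, 24, 27 and 25 changed in the other gates in the order above. The window did not stand out in the 4 steps between Cre gates (exact p = 0.0898 to 0.473).

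**Figure D2:**
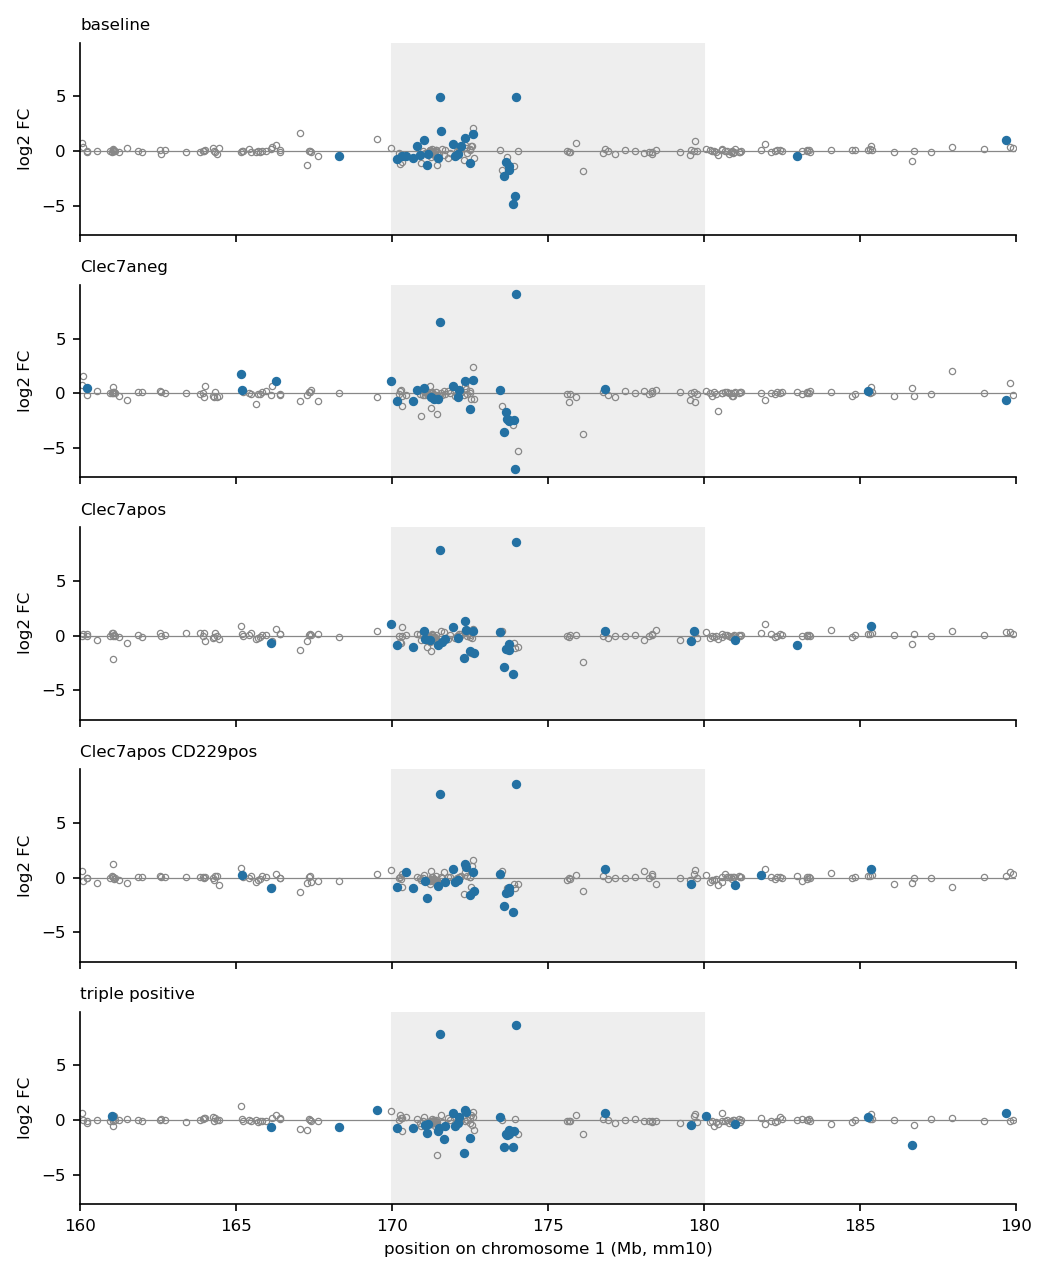
Log2 fold change of Mef2aKO against Cre for tested genes of chromosome 1 between 160 and 190 Mb (mm10), by position, in 5 gates. Filled points had edgeR adjusted p under 0.05, and the band spans 170 to 180 Mb.

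The Mef2aKO effect in the triple-positive gate was tested against that at baseline as an interaction over 12 libraries, and differed for 87 genes upward and 67 downward. Ms4a7 (3.73 ± 0.45, adjusted p = 4.58e-06) and Pcp4 (3.37 ± 0.54, adjusted p = 0.000459) differed most upward. With Cre baseline replicate 1, 2 or 3 as the only control Ms4a7 was 4.33, 3.90 and 2.24 (highest adjusted p = 0.0394) and Pcp4 3.17, 3.61 and 3.29. Igf2r, a mannose phosphate receptor, differed most downward (-2.02 ± 0.43, adjusted p = 0.00991), followed by Postn (-1.89 ± 0.17, adjusted p = 1.11e-08). The Igf2r call ended in 2 fits (adjusted p = 0.0626 without Cre baseline replicate 1 or 0.0626 without Cre baseline replicate 2), and with Cre baseline replicate 3 as the only control (adjusted p = 0.584). The count was 322 without Cre baseline replicate 3 or 232 without Mef2aKO baseline replicate 3.

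Mef2aKO baseline cells sorted by CD229 were compared with each other (CD229pos n = 2, CD229neg n = 3). Ly9 rose from 23.7 ± 10 to 152 ± 8.57 CPM (2.69 ± 0.22, adjusted p = 3.79e-05) and was the only named gene whose call held in every leave-one-out fit. The class II genes H2-Eb1 (3.27 ± 0.51, adjusted p = 0.0168) and H2-Aa (3.08 ± 0.57, adjusted p = 0.0472) were higher. H2-Eb1 had adjusted p = 0.126 without baseline CD229neg replicate 1, 0.161 without baseline CD229neg replicate 2 or 0.174 without baseline CD229pos replicate 2, and H2-Aa adjusted p = 0.224 without baseline CD229neg replicate 1, 0.313 without baseline CD229neg replicate 2, 0.0592 without baseline CD229pos replicate 1 or 0.31 without baseline CD229pos replicate 2. Clec7a rose by 1.28 ± 0.14, adjusted p = 0.00134 (adjusted p = 0.089 without baseline CD229pos replicate 2) and Itgax did not pass (0.76 ± 0.28, adjusted p = 0.611). Axl (1.91 ± 0.23, adjusted p = 0.089 without baseline CD229pos replicate 2) led the disease-associated list (3 of 23 rose, 7 adjusted over the list alone, camera adjusted p = 6.23e-13, estimated 0.0128). Class II genes (4 of 8 rose, 5 adjusted over the list alone, camera adjusted p = 1.05e-08, estimated 0.0517) moved up beside border macrophage markers (1 of 8 rose, 7 adjusted over the list alone, camera adjusted p = 1.25e-08, estimated 0.0906) and monocyte markers (0 of 4 passed, 2 adjusted over the list alone, camera adjusted p = 0.000367, estimated 0.0906). Of 19 genes, 17 were higher, or 5 without baseline CD229neg replicate 1, 4 without baseline CD229neg replicate 2, 29 without baseline CD229pos replicate 1 or 1 without baseline CD229pos replicate 2.

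Against the Cre baseline cells, which were not gated on CD229 (n = 3), Mef2aKO CD229pos cells (n = 2) showed Ctse at 22.7 ± 0.698 and 1.25 ± 0.316 CPM (4.18 ± 0.46, adjusted p = 0.000151). Ccdc162 fell by -2.97 ± 0.36, Ly9 rose by 1.31 ± 0.21, Clec7a rose by 1.28 ± 0.14, adjusted p = 0.000186 and Apoe, the lipid carrier, rose by 1.08 ± 0.14. Counts were 109 higher and 92 lower, or 131 without Cre baseline replicate 1, 107 without Cre baseline replicate 2 or 104 without Mef2aKO baseline CD229pos replicate 1. With Cre baseline replicate 2 as the only control Ly9 did not pass (adjusted p = 0.188). With the PE150 tag as a covariate the log2 fold changes were 4.22 for Ctse and -3.31 for Ccdc162.

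Mef2aKO CD229neg cells against Cre baseline cells (n = 3 each) gave 59 genes higher and 113 lower, or 91 without Cre baseline replicate 1, 90 without Cre baseline replicate 2, 70 without Mef2aKO baseline CD229neg replicate 1, 100 without Mef2aKO baseline CD229neg replicate 2 or 113 without Mef2aKO baseline CD229neg replicate 3. Pdgfrb, a growth factor receptor of pericytes, rose by 3.46 ± 0.42, adjusted p = 0.000462, Ctse by 2.58 ± 0.46, adjusted p = 0.00886 and the receptor gene Cd244a by 2.14 ± 0.25, adjusted p = 0.000422. H2-Eb1 fell from 32 ± 18.6 to 3.73 ± 2.13 CPM (-3.06 ± 0.47, adjusted p = 0.00315) and Ly9 by -1.38 ± 0.21. The class II list (4 of 8 fell, 5 adjusted over the list alone, camera adjusted p = 0.000791, estimated 0.434) and the border macrophage markers (1 of 8 fell, 7 adjusted over the list alone beside 1 higher, camera adjusted p = 0.000496, estimated 0.434) moved down together. With 1 Cre baseline library as the only control, Cd244a passed with each (2.30, 1.99 and 2.17) and Ctse with none (adjusted p = 0.198 to 0.267). Pdgfrb and H2-Eb1 did not pass with replicate 3 (adjusted p = 0.0847 and 0.385), nor Ly9 with replicates 1 and 3 (adjusted p = 0.0629 and 0.0974). The PE150 covariate left Cd244a at 1.78 and H2-Eb1 at -3.36.

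At 6 weeks, Cre CD229neg and unsorted Cre baseline cells were compared (n = 3 each). Zfp618, a zinc finger gene, was 54.3 ± 54.9 CPM against 0.0321 ± 0.0556 CPM (10.19 ± 1.90, adjusted p = 0.000717). Fn1 rose from 1.1 ± 0.581 to 189.7 ± 67.7 CPM (7.41 ± 0.36, adjusted p = 1e-13), Clec7a by 2.02 ± 0.16 and Egr2 by 2.53 ± 0.29. Interferon genes rose (25 of 25 rose, 25 adjusted over the list alone, camera adjusted p = 6.29e-50, estimated 0.000241), led by Oasl2 (1.89 ± 0.12). Mki67 (2.83 ± 0.26) led a rise of cell cycle genes (23 of 26 rose, 26 adjusted over the list alone, camera adjusted p = 2.02e-30, estimated 0.033). Cst7 (2.76 ± 0.19) led disease-associated genes (15 of 25 rose, 16 adjusted over the list alone, camera adjusted p = 6.86e-19, estimated 0.0524), and the chemokine gene Ccl2 (1.97 ± 0.24) inflammatory genes (10 of 20 rose, 11 adjusted over the list alone, camera adjusted p = 2.34e-07, estimated 0.00976). The baseline group carried no PE150 tag while 2 of the 3 CD229neg libraries did. The remaining library against baseline gave 88 calls, with Fn1 at 6.68 and Clec7a at 1.87, and the PE150 covariate gave 755 calls beside 772 (663 higher, 109 lower). The count was 496 without baseline replicate 2 or 457 without CD229neg replicate 3. With 1 Cre baseline library as the only control, Zfp618 passed with none (adjusted p = 0.0678 to 0.14).

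The 6-week CD229 step in Cre cells (n = 3 each) gave 1407 genes higher and 862 lower, or 1268 without CD229pos replicate 2. The calcium channel gene Trpc4 rose by 3.46 ± 0.55, adjusted p = 5.44e-05, Tmem51 by 3.40 ± 0.49, and Ly9 from 43.3 ± 8.3 to 214 ± 10.8 CPM (2.29 ± 0.17). Ccdc162 fell by -2.13 ± 0.23, adjusted p = 1.56e-07 and the metalloproteinase gene Mmp28 by -1.76 ± 0.19. Disease-associated genes rose (17 of 25 rose, 22 adjusted over the list alone, camera adjusted p = 5.67e-16, estimated 0.16), led by Cst7 (1.64 ± 0.15). The cell cycle list rose (24 of 26 rose, 26 adjusted over the list alone, camera adjusted p = 1.26e-13, estimated 0.247), led by Mki67 (1.49 ± 0.21). Class II genes rose (6 of 8 rose, 6 adjusted over the list alone, camera adjusted p = 0.00593, estimated 0.397), led by their regulator Ciita (1.78 ± 0.37), beside border macrophage markers (6 of 8 rose, 7 adjusted over the list alone, camera adjusted p = 0.00416, estimated 0.397), a call that ended without Cre CD229pos replicate 1 (adjusted p = 0.0584). Within the PE150 libraries alone (n = 2 each) the count was 1954, with Trpc4 at 3.71 and Ccdc162 at -2.12. Genes that rose both here and in the WT step at 4 weeks numbered 1179 (334.3 for independent lists), 787 fell in both (206.2), and 6 moved the opposite way.

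The 6-week CD11c step (n = 3 each) gave 1139 genes higher and 1125 lower. Atp6v0d2, a proton pump subunit of osteoclasts and lipid-rich macrophages, rose from 2.48 ± 1.05 to 32.7 ± 6.65 CPM (3.66 ± 0.23, adjusted p = 4.47e-10), Postn by 3.58 ± 0.16 and Slamf7 by 3.05 ± 0.19. Siglecg, an inhibitory lectin, fell by -2.86 ± 0.29, adjusted p = 8.77e-08 and Gpr165 by -2.52 ± 0.27. Itgax rose by 2.05 ± 0.21, Clec7a by 0.86 ± 0.15 and Egr2 by 1.12 ± 0.19, adjusted p = 9.35e-05. Disease-associated genes rose (15 of 25 rose, 16 adjusted over the list alone, camera adjusted p = 8.6e-08, estimated 0.491), led by Lgals3 (1.59 ± 0.16), and glycolysis rose (11 of 16 rose, 11 adjusted over the list alone, camera adjusted p = 1.19e-05, estimated 0.491), led by Slc2a1 (0.62 ± 0.09). Homeostatic genes fell (9 of 20 fell, 11 adjusted over the list alone, camera adjusted p = 9.92e-06, estimated 0.553), led by Slc2a5 (-1.17 ± 0.13). Within the PE150 libraries (n = 2 each) 1277 genes passed, with Atp6v0d2 at 3.24 and Siglecg at -2.90.

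The CD11c step was measured in 3 sets of libraries. Among 12571 genes tested in all 3, 305 rose in each and 224 fell in each, Postn ranking first of those that rose (4.47 at 4 weeks, 4.22 at 5 and 3.58 at 6). The 4-week and 5-week steps shared 730 higher genes (103.4 for independent lists) and 774 lower ones (108.9), with 0 in opposite directions in edgeR's calls. The 4-week and 6-week steps shared 408 and 286, with 220 opposite, and the 5-week and 6-week steps 363 and 248, with 104 opposite. Whether the steps differ between the experiments was not tested, since week, genotype and batch change together.

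**Figure D3:**
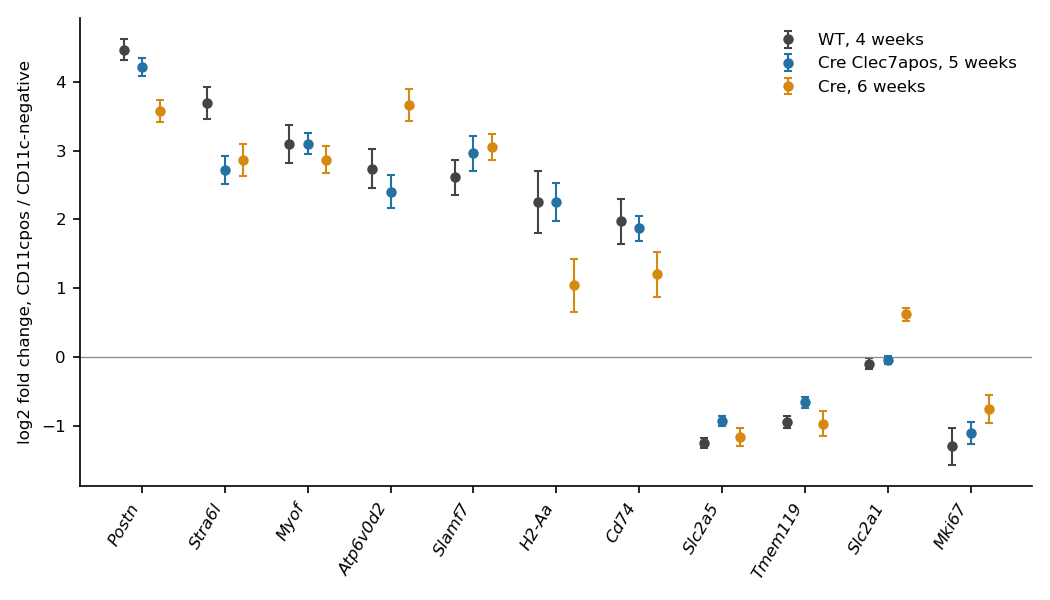
Log2 fold change of CD11cpos against CD11c-negative CD229pos cells in WT at 4 weeks, Cre Clec7apos at 5 weeks and Cre at 6 weeks, for 11 genes. Bars are standard errors from edgeR with n = 3 per group.

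Egr2KO baseline cells (n = 2) against Cre baseline cells (n = 3) gave 20 genes higher and 4 lower, or 2 to 147 without any 1 of the 5 libraries. Coro2a, an actin-binding gene, fell from 84.9 ± 7.63 to 43.9 ± 1.36 CPM (-0.95 ± 0.10, adjusted p = 4.03e-06). Tnfsf8, a ligand of the tumour necrosis factor family, was lower by -1.50 ± 0.27, adjusted p = 0.00954 (adjusted p = 0.124 without Cre replicate 2 or 0.621 without Egr2KO replicate 1). The immediate early genes Fosb (5.61 ± 0.90, adjusted p = 0.00286) and Klf4 (3.33 ± 0.47, adjusted p = 0.00103) were higher. They had adjusted p = 0.0516 without Cre replicate 2 or 0.88 without Egr2KO replicate 1 for Fosb and 0.88 without Egr2KO replicate 1 for Klf4. With Cre baseline replicate 3 as the only control Fosb, Klf4 and Tnfsf8 did not pass (adjusted p = 0.93, 0.455 and 1), nor Tnfsf8 with replicate 1 (adjusted p = 0.0565), while Coro2a passed with each (-0.94, -1.08 and -0.82). The immediate early list moved up (6 of 20 rose, 15 adjusted over the list alone, camera adjusted p = 4.95e-21, estimated 0.11). Both Egr2KO baseline libraries and no Cre baseline library carried the PE150 tag, so genotype and tag differ together in this pair. With the tag as a covariate, estimated from the cuprizone groups, Coro2a stood at -1.04 (adjusted p = 2.12e-06).

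In CD229neg cells at 6 weeks (n = 3 each), Egr2KO gave 19 genes higher and 6 lower, or 8 without Cre replicate 1, 11 without Cre replicate 2, 14 without Cre replicate 3, 2 without Egr2KO replicate 2 or 11 without Egr2KO replicate 3. Coro2a fell from 76.8 ± 5.33 to 50.3 ± 0.359 CPM (-0.61 ± 0.09, adjusted p = 0.002), after the sialyltransferase gene St8sia6 (-1.11 ± 0.21, adjusted p = 0.0162, adjusted p = 0.064 without Cre replicate 2, 0.129 without Cre replicate 3, 0.103 without Egr2KO replicate 1 or 0.326 without Egr2KO replicate 2). Tmem51 rose by 3.28 ± 0.52, adjusted p = 0.00347 (adjusted p = 0.168 without Egr2KO replicate 2). Itgax (-0.12 ± 0.23, adjusted p = 0.926) and Clec7a (0.14 ± 0.15, adjusted p = 0.855) did not pass, and disease-associated genes moved up as a list (1 of 25 rose, 16 adjusted over the list alone, camera adjusted p = 1.04e-13, estimated 0.242). Within the PE150 libraries (n = 2 each), 26 genes passed, with Coro2a at -0.68 and Tmem51 at 3.02.

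Egr2KO CD229pos cells (n = 3 each) had 187 genes higher and 138 lower, or 125 without Cre replicate 1, 78 without Cre replicate 3, 72 without Egr2KO replicate 2 or 98 without Egr2KO replicate 3. Tmem51 rose from 4.8 ± 1.7 to 20.6 ± 5.49 CPM (2.09 ± 0.31, adjusted p = 0.000476), Lgi2 by 1.54 ± 0.21 and the growth factor binding gene Igfbp5 by 1.47 ± 0.22. Atp6v0d2 was lower by -1.41 ± 0.36, adjusted p = 0.036 (adjusted p = 0.0959 without Cre replicate 2, 0.157 without Cre replicate 3, 0.0709 without Egr2KO replicate 1, 0.158 without Egr2KO replicate 2 or 0.11 without Egr2KO replicate 3), and Mmp12 by -1.27 ± 0.26, adjusted p = 0.00876 (adjusted p = 0.0874 without Cre replicate 3). Interferon genes rose (12 of 25 rose, 22 adjusted over the list alone, camera adjusted p = 1.92e-16, estimated 0.051), led by Irf7, a master regulator of that response (0.84 ± 0.10), and Oasl2 (0.69 ± 0.10), and glycolysis moved up (5 of 16 rose, 11 adjusted over the list alone, camera adjusted p = 1.09e-09, estimated 0.319). In the PE150 libraries (n = 2 each), 263 genes passed, with Tmem51 at 2.02, Igfbp5 at 1.30 and Irf7 at 0.84.

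In CD229pos CD11cpos cells (n = 3 each), Egr2KO gave 16 genes higher and 17 lower, or 3 to 13 without any 1 of the 6 libraries. Notch4 rose from 42.1 ± 1.5 to 96.2 ± 8.49 CPM (1.19 ± 0.15, adjusted p = 0.000237), a call that held in all 6 of these fits. Tmem51 rose by 1.83 ± 0.32, adjusted p = 0.00906 (adjusted p = 0.0629 without Cre replicate 2, 0.0927 without Cre replicate 3, 0.0566 without Egr2KO replicate 1 or 0.0512 without Egr2KO replicate 2). Itga4, an integrin subunit, was lower by -1.32 ± 0.26, adjusted p = 0.022, and Atp6v0d2 by -1.07 ± 0.19, adjusted p = 0.0128, and these calls ended in every leave-one-out fit (adjusted p = 0.0557 to 0.142 without any 1 of the 6 libraries for Itga4, and 0.0506 to 0.114 without any 1 of the 6 libraries for Atp6v0d2). Itgax did not pass (-0.09 ± 0.21, adjusted p = 0.924), and 1 interferon gene rose (1 of 25 rose, 11 adjusted over the list alone, camera adjusted p = 4.82e-10, estimated 0.269). In the PE150 libraries (n = 2 each) Notch4 was 1.21, Itga4 -1.33 and Atp6v0d2 -0.93, with 44 genes past the test. The Egr2KO effect in this gate did not differ from that in CD229neg cells for any gene in edgeR's interaction test (0 calls, 488 genes at unadjusted p under 0.05, 0 calls in DESeq2, 23 without a filter), Egr2 included (0.44 ± 0.31, adjusted p = 0.995).

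The unsorted population at 5 weeks compared Egr2KO with Cre (n = 2 each), with 37 genes higher and 77 lower. Atp6v0d2 fell from 9.43 ± 2.04 to 0.981 ± 0.151 CPM (-3.28 ± 0.35, adjusted p = 0.000228), Itga4 by -1.97 ± 0.21 and St8sia6 by -1.90 ± 0.14. Synpo, an actin-linked protein, rose by 2.50 ± 0.33, adjusted p = 0.000996 and the anion transporter Slc26a11 by 1.77 ± 0.24. Itgax fell by -0.85 ± 0.10, Clec7a by -0.55 ± 0.07, adjusted p = 0.00132, and Ly9 did not pass (0.04 ± 0.07, adjusted p = 0.915). H2-Aa (-1.60 ± 0.15) led a fall of class II genes (4 of 8 fell, 6 adjusted over the list alone, camera adjusted p = 6.33e-08, estimated 0.581), beside border macrophage markers (3 of 8 fell, 5 adjusted over the list alone, camera adjusted p = 1.39e-05, estimated 0.581). The count was 310 without Cre replicate 1 or 176 without Cre replicate 2. Genes called in the same direction here and in the sorted CD11cpos gate numbered 7 higher (0 for independent lists) and 8 lower (0.1), and for CD229pos cells 18 (0.6) and 16 (0.8), with 0 opposite in edgeR's calls in either pair.

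Over the 30 comparisons, camera put the lysosome list past the test upward in 10 and downward in 5, complement and Fc receptors in 9 and 4, cholesterol export in 12 and 2, cholesterol synthesis in 8 and 3, TREM2-DAP12 signaling in 1 and 1, and lineage transcription factors in 0 and 1. Of these calls 1 for cholesterol export and 1 for cholesterol synthesis held at the estimated correlation. The Polycomb list passed in none (lowest adjusted p = 0.0522). Astrocyte markers passed downward in 4, monocyte markers upward in 1 and downward in 4, endothelial markers upward in 2 and downward in 1, and neuron markers upward in 1 of the 29 comparisons that measured enough of them, none at the estimated correlation. Oligodendrocyte and dendritic cell markers passed in none (lowest adjusted p = 0.169 and 0.133). The T and NK cell, B cell and neutrophil lists had 1 measured gene each and were not tested.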

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

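The tests of explanations for the chromosome 1, class II and immediate early gene patterns were chosen after the results were seen, while the interaction tests were planned.

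Among the gene values of the 2 groups of 4 libraries, 5 of 64 (7.8%) had a library far from the other 3, and chance marks about 1 in 20 groups. In Trem2KO CD229neg cells replicate 3 lay apart for Apoc1 (2.7 CPM, others 0.982 to 1.25), Cxcl14 (0.352 CPM, others 0) and Kbtbd11 (3.63 CPM, others 6.16 to 6.44). In Trem2KO CD229pos cells replicate 2 lay apart for Folr2 (19.1 CPM, others 24 to 24.5) and replicate 4 for Slc5a10 (3.1 CPM, others 6.84 to 7.19).

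The CD229 step at 4 weeks differed between Trem2KO and WT for 1871 genes in the interaction test. Trem2KO minus WT was 2.68 for Adcy8, 0.97 for Clec7a, -1.96 for Egr2, 2.85 for H2-Aa, -2.42 for Kbtbd11, -2.57 for Notch4, 1.52 for Oas2, -2.62 for Pacsin1, 2.69 for Setbp1 and -0.56 for Slc2a1 on the log2 scale. The interferon (camera adjusted p = 8.04e-06) and glycolysis lists (camera adjusted p = 0.000531) differed too, but not at the estimated correlation (0.796 each). The Mef2aKO effect differed between the triple-positive gate and baseline for 154 genes, by -2.02 for Igf2r, 3.73 for Ms4a7, 3.37 for Pcp4 and -1.89 for Postn.

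Genes changed in Mef2aKO crowded between 170 and 180 Mb of chromosome 1, away from Mef2a on chromosome 7. Of genes changed in at least 1 gate, 34 of 44 in the window had 1 sign over all 5 against 740 of 1600 elsewhere. A strain variant of the Mef2a line would give this (one-sided Fisher's exact p = 3.43e-05). Without the Ifi200 family and the interferon list the window still stood out in every gate (highest exact p = 4.29e-05), which argues against an interferon response or shared reads as the whole cause. A candidate is chromosome 1 sequence of another strain kept near these genes. The window also passed in Trem2KO baseline cells (5 of 92 genes, adjusted p = 0.0459), so crowding may extend beyond the Mef2a line. The Trem2KO calls fell from 73 to 6 with the compared groups only. Regulation of this region by Mef2a was not tested and stays open.

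MHC class II genes varied with border macrophage markers between baseline libraries, although the CD44, CD45 and CD11b low gate would exclude most such cells. Over 11 Cre and Mef2aKO baseline libraries the scores had r = 0.95 and rho = 0.96 (permutation p = 4e-05 each, adjusted p = 0.00016, 4 relations computed), r = 0.93 without the 2 farthest libraries, and r = 0.95 in the 8 libraries without the PE150 tag. In the 6 WT and Trem2KO baseline libraries r was 0.96 and rho 1 (permutation p = 0.00299, adjusted p = 0.00299, r = 0.9 without the 2 farthest). Mrc1 stood at 99.4 and 78.2 CPM in Cre replicates 1 and 2 and 17.9 CPM in replicate 3, and Cd163 at 12.8, 15.8 and 0.78 CPM, so a few border macrophages in some sorts may account for part of the baseline class II values. The groups of the 11 libraries differed in both scores, so p does not isolate variation within them. A genotype effect on class II genes stays open. Cd74 and H2-Ab1 stayed lower in Mef2aKO against each Cre library alone. With replicate 3 they were -0.98 and -1.39 (-2.00 and -2.49 by default), H2-Aa -1.17 and, in CD229neg cells, H2-Eb1 -1.54.

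The same source was tested for H2-Aa, H2-Ab1, H2-Eb1 and Cd74 in the CD11cpos gates, although H2-Aa and H2-Eb1 did not pass at 6 weeks (adjusted p = 0.066 and 0.15) and the class II list passed camera only at 5 weeks (adjusted p = 0.458, 0.00883 and 0.141 at 4, 5 and 6 weeks, estimated 0.156 at 5). These 4 genes had median log2 fold changes of 1.76, 1.81 and 1.04, while the 8 border macrophage markers had -1.21, 0.14 and -1.10. Single markers went both ways, the highest (1.28, 1.16 and 0.43) under the class II median. Stab1 (1280 to 1380 CPM) did not follow Mrc1 (18.3 to 74.9) over WT baseline libraries, so the medians leave this source open. Ms4a7 rose at 4 and 5 weeks. Other sources were not tested, and class II expression by CD11cpos microglia is a hypothesis.

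Immediate early genes, high in Egr2KO baseline replicate 1, also varied within groups. Over 58 cuprizone libraries, same-numbered libraries of a genotype and diet deviated together (statistic 8.14 against a permuted mean of 0.05, one-sided permutation p = 2e-04), as handling shared by the gates of 1 sort would give. With the PE150 tag as a covariate the list kept a median log2 fold change of 1.6 in Egr2KO baseline cells (camera adjusted p = 1.14e-18, estimated 0.111). The rise of its mean score was 1.73 ± 0.48 without and 1.90 ± 0.56 with the tag (linear model, ± SE, 23 libraries). The tag gave -0.17 ± 0.27 in 6-week groups (2 of 3 libraries each), but at baseline it follows genotype and was not tested. Handling at the sort may explain part of these differences, and an effect of Egr2 loss was not tested apart from it.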

How the results depend on the processing

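Fits with 1 baseline control library or split by PE150 and the other table joins were chosen after seeing the data. All others were planned. Counts of changed genes stayed within 1.5 times the default in 303 fits and left that range in 115, and of the values of named genes 3790 kept their call, 90 lost it, 15 gained it and none reversed. The RLE size factors left all 30 counts within that range, and both other joins of the 4-week tables left their 8 counts within it. In the brackets that follow, the default count is given.

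Without a filter, counts became Trem2KO baseline 288 (73), Mef2aKO interaction 371 (154), Mef2aKO baseline CD229 step 184 (19), Mef2aKO baseline CD229pos 469 (201), Mef2aKO baseline CD229neg 435 (172), Egr2KO baseline 166 (24), Egr2KO CD229neg 167 (25), Egr2KO CD229pos 834 (325), Egr2KO CD229pos CD11cpos 162 (33), Egr2KO interaction 23 (0) and Egr2KO whole population 339 (114). With DESeq2 they were Trem2KO baseline 115 (73), Mef2aKO interaction 237 (154), Mef2aKO baseline CD229 step 62 (19), Mef2aKO baseline CD229pos 311 (201), Egr2KO baseline 41 (24) and Egr2KO CD229pos CD11cpos 61 (33). The share of higher genes moved as well: 55 of 288 for Trem2KO baseline without a filter against 5 of 73, 85 of 166 and (DESeq2) 26 of 41 for Egr2KO baseline against 20 of 24, and 57 of 162 without a filter for Egr2KO CD229pos CD11cpos against 16 of 33. The cause was not tested.

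Fitting the compared groups only gave Trem2KO baseline 6 (73), Mef2aKO baseline 93 (507), Mef2aKO interaction 66 (154), Mef2aKO baseline CD229 step 32 (19), Egr2KO baseline 1 (24), Egr2KO CD229neg 89 (25), Egr2KO CD229pos 120 (325) and Egr2KO CD229pos CD11cpos 95 (33). Fewer libraries then estimate the spread, and in the whole-population experiment this alternative could not be run, since it holds no other groups. The replicate block gave Mef2aKO baseline CD229 step 12 (19), Egr2KO baseline 51 (24), Egr2KO CD229pos 570 (325), Egr2KO CD229pos CD11cpos 66 (33) and Egr2KO whole population 279 (114), and the nested replicate block Trem2KO interaction 3237 (1871) and 5-week CD229 step 1381 (730); here the cause was not tested.

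The PE150 covariate gave Mef2aKO baseline CD229 step 41 (19), Egr2KO baseline 56 (24), Egr2KO CD229neg 39 (25), Egr2KO CD229pos 564 (325) and Egr2KO CD229pos CD11cpos 63 (33). PE150 libraries only gave 6-week CD11c step 1277 (2264), and libraries without PE150 only 6-week diet step 88 (772). With baseline control replicate 1, 2 and 3 as the only control, counts were 4-week diet step 2076, 3584 and 1908 (3850), Trem2KO baseline 12, 382 and 113 (73), 5-week diet step 3451, 2490 and 1237 (3808), Mef2aKO interaction 227, 146 and 70 (154), Mef2aKO baseline 465, 320 and 137 (507), Mef2aKO baseline CD229pos 65, 56 and 59 (201), Mef2aKO baseline CD229neg 82, 56 and 21 (172), 6-week diet step 648, 442 and 259 (772) and Egr2KO baseline 37, 71 and 1 (24). These last 3 settings leave fewer libraries. Of the 252 calls of gene lists over all comparisons, 18 held with an estimated correlation.

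With each library left out in turn, where any count left the range, counts ran from lowest to highest as follows: Trem2KO baseline 34 to 206, Trem2KO CD229neg 1362 to 2380, Mef2aKO baseline 282 to 815, Mef2aKO interaction 104 to 322, Mef2aKO Clec7aneg 299 to 666, 5-week CD229 step 343 to 608, Mef2aKO Clec7apos 315 to 377, 5-week CD11c step 1169 to 1483, Mef2aKO Clec7apos CD229pos 425 to 549, Mef2aKO triple-positive 380 to 540, Mef2aKO baseline CD229pos 104 to 205, Mef2aKO baseline CD229neg 70 to 255, Mef2aKO baseline CD229 step 1 to 29, 6-week diet step 457 to 1139, Egr2KO baseline 2 to 147, 6-week CD229 step 1268 to 2403, Egr2KO CD229neg 2 to 17, Egr2KO CD229pos 72 to 482, Egr2KO CD229pos CD11cpos 3 to 13 and Egr2KO whole population 107 to 310. Where an arm was left with 1 library, it was taken to vary like the other groups.

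Of 25124 genes, 12387 to 13204 had enough counts to be tested in an experiment, so depth limited what was seen of the rest.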

Other observations

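The genes named below were chosen after their values were seen, while the tests of other splits of the libraries were planned. Outside the chromosome 1 window, several genes changed in all 5 Mef2aKO gates. Hmga2, a chromatin protein of fetal and dividing cells, had at most 2 counts in any of the 15 Cre libraries of the 5-week experiment and 21 to 88 counts in each of the 14 Mef2aKO libraries. Spred3, an inhibitor of growth factor signaling, changed by -3.07, -2.97, -3.21, -3.88 and -2.65 on the log2 scale (baseline, Clec7aneg, Clec7apos, Clec7apos CD229pos and triple positive), and the oxidase gene Cybb by -2.32, -3.69, -2.08, -1.93 and -1.65. Pdgfrb was higher by 3.76, 3.29, 4.02, 3.15 and 2.93, and Nccrp1 by 2.12, 1.99, 3.48, 3.11 and 2.74. Adjusted p was at most 0.0032 for these 4 genes. With Cre baseline replicate 3 as the only control the baseline change of Cybb was -0.75 (adjusted p = 0.455), and the other 3 genes passed at baseline with each Cre library alone.

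Genes within 10 Mb of the targeted gene were tested for an excess of changed genes in 13 comparisons (one-sided Fisher's exact tests), and none passed after adjustment over the 13 (lowest adjusted p = 0.0568). The largest excesses were 8 of 105 near Egr2 in Egr2KO CD229pos cells (2.6 expected) and 5 of 30 near Mef2a in triple-positive cells (1.4 expected). Of 10 Mb windows over the genome, 8 passed the test besides those of chromosome 1 in Mef2aKO (adjusted p = 0.017 to 0.0459). They were 170 to 180 Mb of chromosome 1 in Trem2KO baseline cells, and 30 to 40 Mb of chromosome 17 and 60 to 70 Mb of chromosome 18 in Mef2aKO Clec7aneg cells. In Mef2aKO Clec7apos CD229pos cells they were 10 to 20 Mb of chromosomes 19 and 2 and 80 to 90 Mb of chromosome 7. In Egr2KO they were 30 to 40 Mb of chromosome 19 in CD229pos cells and 60 to 70 Mb of chromosome 10, which holds Egr2, in the whole population.

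Other splits of the compared libraries into groups of the same sizes were fitted without the other groups. With 3 libraries a side there are 10 splits, too few for a share under 0.05. In 1 of the 10 splits, the real one, as many genes passed for these results, with a highest other count of 0: the 4-week diet, CD229 and CD11c steps (3121, 6382 and 3686), the 5-week diet, Clec7a, CD229 and CD11c steps (3001, 5140, 617 and 2269), the 6-week steps in the same order (577, 2077 and 1818), and Mef2aKO Clec7apos, Clec7apos CD229pos and triple-positive cells (565, 819 and 893). The real and highest other counts were 238 and 12 for Mef2aKO baseline CD229neg, 120 and 8 for Egr2KO CD229pos, and 95 and 1 for Egr2KO CD229pos CD11cpos.

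In 2 of the 10 splits as many genes passed for Trem2KO baseline (real 6, highest other 16), Mef2aKO baseline (93 and 821) and Egr2KO CD229neg (89 and 250). For Trem2KO and Mef2aKO baseline the highest split set the 3 libraries with the most border macrophage RNA against the other 3, which points to that structure of the samples. For Egr2KO CD229neg it kept both libraries without the PE150 tag together, and the PE150 libraries alone gave 26 genes.

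Of 35 splits, 1 gave as many genes for Trem2KO CD229neg (3079), Trem2KO CD229pos (6885) and the CD229 step in Trem2KO (3850), with a highest other count of 0, a share under 0.05. For the Trem2KO interaction 2 of 100 drawn splits gave as many (real 2491, highest other 2647). For Mef2aKO 8 did (real 66, highest other 762), and for Egr2KO 100 (real 0, highest other 584). Such splits also break the genotype effect of each gate, so they cannot test an interaction, and chance was not excluded. The highest Mef2aKO split grouped the baseline libraries by border macrophage RNA as above.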
